A study of Homo sapiens with 16 samples.

How the data were processed

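The study measured RNA from A673 cells of the clone Asp14 on 16 Affymetrix arrays after doxycycline induced a hairpin against EWS-FLI1. Samples were grouped by the hours given in the labels, 0 h (4 arrays), 18 h (3), 36 h (3), 53 h (2), 72 h (2) and 96 h (2), and 0 columns of other samples were present. Labels number the replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical only.

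The authors deposited log2 expression values per probe set made with GCRMA, per the submitters' processing notes. GCRMA adjusts background by probe sequence and normalizes between arrays. The version of GCRMA, its settings and whether the 16 arrays were processed together are not given in the sources used here. That the scale is log2 was read from the values, which ran from 0.388 to 15.2. GCRMA compresses dim values, so changes of genes near background are less certain than those of bright genes, and no detection calls were used here. Of 22277 probe sets, 62 of them controls, 19070 had 1 gene symbol in the annotation of the platform, 1043 had several and 2164 had none. Only those with 1 symbol were named, and 19058 of them matched the RefSeq gene table by Entrez identifier, with 0 symbols changed.

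For each of 11963 genes the probe set with the highest mean over all arrays was used, and 4310 genes had over 1 probe set. Genes needed a log2 value of at least 4 on at least 2 arrays, which left 7304 tested and 4659 left out. Models were fitted in R 4.3.3 with limma 3.58.1 (lmFit with 1 mean per time group over all 16 arrays, contrasts.fit, and eBayes with a trend, 10 residual degrees of freedom) and data.table (version 1.17.8) for reading the files. Adjusted p-values are those of limma after Benjamini-Hochberg adjustment over genes within a comparison, with a threshold of 0.05. Each time was compared with 0 h, 96 h was compared with 18 h, and a moderated F test covered the time course. The comparison of 96 h with 72 h was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

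The 20 gene lists, the tests and the alternatives, other than those named at the end, were fixed before the data were examined. The lists held EWS-FLI1-activated and EWS-FLI1-repressed genes, the E2F and RB family, E2F targets, G2/M, extracellular matrix, actin and adhesion, neural, mesenchymal, p53, interferon, integrated stress response, respiratory chain, mitochondrial ribosome, glycolysis and hypoxia, cholesterol synthesis and ribosome biogenesis genes, and markers of blood, epithelial and endothelial cells. No gene was in more than 1 list. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01 without a trend, adjusted over 102 tests of lists and planned comparisons. Alternatives were camera with an estimated correlation and fry, which tests whether members move on balance in 1 direction without comparing them with other genes.

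Named genes followed a fixed rule. FLI1, EWSR1 and the E2F and RB family were taken at all times. At 96 h against 0 h the 12 highest and 12 lowest log2 changes were taken among genes past the threshold whose arrays did not overlap between the groups, with 5 and 5 at 18 h and for 96 h against 18 h, and 3 and 3 at 36 h, 53 h and 72 h. For each other list called in any comparison, the 4 members with the smallest adjusted p at 96 h against 0 h were taken. Other genes are named as chosen after their values were seen. Lower bounds on fold changes set the mean of the brighter group against log2 4 and were given only where all probe sets of the gene were below log2 4 on every array of the dimmer group. They allow for dim values only and not for the spread between arrays of the brighter group. For PDGFRA, another of whose probe sets was above log2 4 at 0 h, the bound is that of the probe set used alone.

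Samples of 0 h, 18 h and 36 h were taken as pairs by the replicate numbers in the labels, which state no pairing. Deviations from the group means correlated across genes between arrays of the same number at 0.632, 0.545 and 0.508 for 0 h with 18 h, 0.304, 0.214 and 0.286 for 0 h with 36 h, and 0.366, 0.244 and 0.331 for 18 h with 36 h. Replicate 1 at 0 h correlated at -0.588 and -0.544 with replicates 2 and 3 at 18 h. Numbers 2 and 3 were not told apart in this way. Replicate 3 at 0 h correlated at 0.550 with replicate 2 at 18 h, and replicate 2 at 0 h at 0.467 with replicate 3 at 18 h. Pairs of these 2 numbers are therefore uncertain. The models without a block were written as the main ones and a block was an alternative.

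The models were tested on simulated data with 7304 genes. Of genes changed by 1 on the log2 scale, 91.0% were recovered in the design of 18 h against 0 h and 85.1% in that of 96 h against 0 h, with 7 and 11 false calls. Of genes changed by 0.5, 47.8% and 35.8% were recovered. In the same test camera called the shifted list in each comparison and 1 of 16 unshifted lists at 18 h. Simulated genes varied independently of each other, so this cannot show false list calls that arise when members move together. For deviations shared between arrays, the covariance across 2 probe sets of a gene was divided by that for the same probe set, over 1022 genes with limits from 1000 bootstrap samples of genes, and this ratio was also tested on simulated data.

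Alternatives covered the filter, the variance trend, the replicate block, the groups in the model, a second quantile normalization, centring of arrays, the choice of probe set, array weights, each array left out in turn, a threshold on the log2 change, the set test and other splits of the 0 h arrays. Averaging replicates 2 and 3, a batch inferred from the values as a block, dim values set to log2 4, differences within replicate pairs for the E2F targets less the G2/M genes, and leaving out replicate 4 at 0 h with replicate 2 at 53 h and at 96 h were chosen after seeing the data.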

Results

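Gene expression was measured in A673 cells, an established Ewing sarcoma line whose driver is EWS-FLI1, a fusion of the EWSR1 and FLI1 genes that acts as an aberrant transcription factor. The clone used, Asp14, carries a short hairpin RNA against the fusion that is switched on by doxycycline, given at 1 ug/ml. RNA was taken at 0 h (n = 4 arrays), 18 h (n = 3), 36 h (n = 3), 53 h (n = 2), 72 h (n = 2) and 96 h (n = 2) after doxycycline, 16 Affymetrix arrays in all. The upper quartile of log2 values per array lay between 8.08 and 8.18, and the number of arrays limits the precision. The 3' less the 5' signal of ACTB, a measure of RNA quality, ranged from 1.47 to 2.45 on the log2 scale and was highest at 36 h (2.09 to 2.45 in its 3 arrays). The title of the series places the study on the relation between EWS-FLI1 and the E2F transcription factors, which drive entry into S phase. All untreated arrays were taken at 0 h, so time in culture and doxycycline itself cannot be told apart from loss of the fusion.

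FLI1, the target of the hairpin, fell at the earliest time and stayed low. The brightest of its 3 probe sets read 10.08 ± 0.07 on the log2 scale at 0 h (SD, n = 4) and was lower on all 12 arrays after doxycycline. Its log2 change against 0 h was -3.20 ± 0.14 (SE) at 18 h, -3.67 ± 0.14 at 36 h, -3.28 ± 0.16 at 53 h, -3.08 ± 0.16 at 72 h and -3.35 ± 0.16 at 96 h. These correspond to 9.20-fold, 12.7-fold, 9.71-fold, 8.47-fold and 10.2-fold lower levels, with limma adjusted p between 5.0e-08 and 1.1e-09. At 96 h the other probe sets of FLI1 changed by -3.84 and -2.54. Both were below log2 4 on each array at 96 h, so the sizes of these changes are uncertain. Whether each probe set lies in the part of FLI1 kept in the fusion was not analysed here. EWSR1, the other partner of the fusion, fell from 36 h on, with log2 changes of -0.59 ± 0.09 at 36 h, -0.74 ± 0.10 at 53 h, -0.84 ± 0.10 at 72 h and -0.51 ± 0.10 at 96 h. Its change of -0.21 at 18 h missed the threshold (limma adjusted p = 0.0887), and passed it when all probe sets of the gene were averaged (adjusted p = 0.0167).

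**Figure D1:**
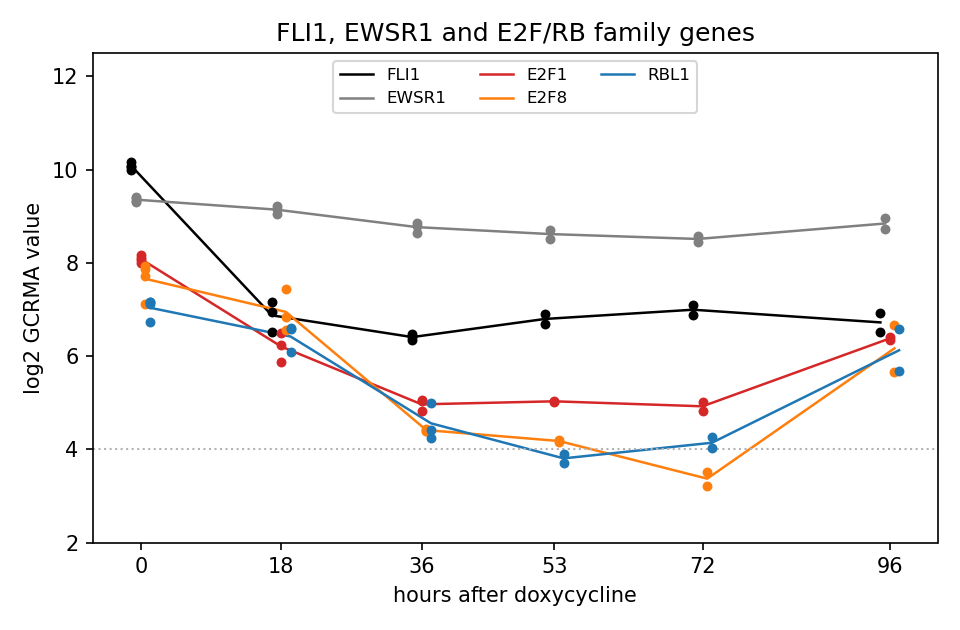
Log2 expression (vertical axis) against hours after doxycycline (horizontal axis), with 1 point per array, set slightly apart, and lines through group means; the dotted line marks log2 4. FLI1 dropped from 10.08 at 0 h to 6.87 at 18 h and stayed between 6.41 and 6.99.

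The comparison of 18 h with 0 h asks what changed first. PDGFRA, a receptor for platelet-derived growth factor, was at least 19.6-fold higher by the probe set used (n = 3 against 4). IGFBP5, which binds insulin-like growth factors, rose by 4.54 ± 0.44 on the log2 scale (SE), and the stress-induced GDF15 and DDIT4 by 4.19 ± 0.59 and 3.87 ± 0.52. SPRY1, an inhibitor of receptor tyrosine kinase signalling, rose by 3.60 ± 0.26. The probe set used for PDGFRA was below log2 4 on all 4 arrays at 0 h, while another of its 3 probe sets was not. GDF15 was at or above it on 1 of 4 and SPRY1 on 2 of 4. With all probe sets of a gene averaged, the changes were smaller, 1.63 for PDGFRA, 1.59 for IGFBP5, 2.10 for GDF15 and -1.49 for KALRN. Such averages include probe sets below the filter on low values, which by themselves make a change smaller. Only 1 of 2 probe sets of GDF15 and of KALRN reached that filter. Where all probe sets of a gene were below log2 4 on every array of a group, the fold is given as a lower bound, with log2 4 in place of the dim values. Such bounds leave out the spread between arrays of the brighter group. PCDH8, a protocadherin, was at least 6.32-fold lower, the histone methyltransferase SUV39H2 at least 5.40-fold, KALRN at least 3.87-fold and KMO at least 2.78-fold (limma adjusted p between 6.2e-08 and 7.3e-05). For each of these genes all 3 arrays at 18 h lay beyond all 4 at 0 h, as the rule for naming them required. In total 2150 of 7304 genes passed the threshold, 1078 higher and 1072 lower. This count was 1355 without replicate 1 at 18 h, 1269 with replicates 2 and 3 averaged and 3546 with array weights, and 400 genes also changed by at least 1 on the log2 scale.

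At 36 h against 0 h, PDGFRA was at least 144-fold higher by the probe set used (n = 3 against 4), and rose by 2.78 on the log2 scale with its probe sets averaged. The chemokine CXCL14 was at least 46.1-fold higher and DKK1, a secreted Wnt inhibitor repressed by the fusion in earlier work, at least 23.8-fold higher. CALCB, a calcitonin-related peptide gene and a known target of the fusion, fell by 5.00 ± 0.32 (log2, SE), and it was at or above log2 4 on 1 of 3 arrays at 36 h. The replication factors MCM10 and CDC45 were lower as well, MCM10 with a change of -4.89 ± 0.27 and CDC45 at least 22.7-fold. Limma adjusted p for these 6 genes lay between 1.2e-09 and 8.8e-08, and 4772 genes passed the threshold, 2427 higher and 2345 lower.

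At 53 h and at 72 h against 0 h, MGP, a matrix protein of cartilage and vessel walls, was at least 360-fold and at least 1099.9-fold higher (n = 2 against 4 at each time). DKK1 was at least 128-fold and at least 232-fold higher, and PAMR1 at least 110.5-fold and at least 371-fold. CALCB was at least 27.5-fold lower and PPP1R1A, an inhibitor of protein phosphatase 1, at least 24.6-fold lower at both times. UTS2, the gene of urotensin, fell by 5.24 ± 0.92 on the log2 scale at 53 h (-2.63 with its probe sets averaged), and PLK1, a mitotic kinase, was at least 18.9-fold lower at 72 h. Limma adjusted p was at most 0.000195 for each of these genes. The threshold was passed by 4845 genes at 53 h (2322 higher, 2523 lower) and by 5003 at 72 h (2142 higher, 2861 lower).

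At 96 h against 0 h, MGP was at least 635-fold higher, IGFBP3 at least 355-fold, PAMR1 at least 175-fold, VCAN at least 143-fold, FGL2 at least 114-fold, DKK1 at least 84.1-fold, SPP1 at least 68.6-fold, LAMA4 at least 67.6-fold and HTRA1 at least 50.8-fold (n = 2 against 4). TDO2, which degrades tryptophan, rose by 7.99 ± 0.37 on the log2 scale (SE), COL6A3 by 7.93 ± 0.54 and IGFBP7 by 7.85 ± 0.50, with COL6A3 at or above log2 4 on 2 of the 4 arrays at 0 h. CALCB was at least 27.5-fold lower, DLG2 at least 25.5-fold, PPP1R1A at least 24.6-fold, CLDN1 at least 19.4-fold, CDH8 at least 14.3-fold and ADRB3 at least 11.3-fold. The log2 change was -6.13 ± 0.92 for UTS2, -5.22 ± 0.26 for the kinase gene PRKCB, -4.93 ± 0.23 for GYG2, -4.85 ± 0.35 for the Wnt modulator DKK2, -4.42 ± 0.23 for HOOK1 and -4.34 ± 0.31 for CNTNAP2. UTS2 and GYG2 were at or above log2 4 on 1 of 2 arrays at 96 h. With all probe sets averaged, LAMA4 changed by 2.36, UTS2 by -3.08 and CDH8 by -2.76. Only 3 of 5 probe sets of LAMA4 and 1 of 2 of UTS2 and of CDH8 reached the filter on low values. Limma adjusted p was at most 7.1e-05 for each of these 24 genes, and both arrays at 96 h lay beyond all 4 at 0 h, as the rule for naming them required. In total 4440 genes passed the threshold, 1830 higher and 2610 lower. The median change of all genes was -0.11 at 72 h and -0.10 at 96 h against 0 h and -0.11 at 96 h against 18 h, and list medians with arrays centred are given beside the smaller changes.

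Genes known to be activated by EWS-FLI1 fell at every time. The list was drawn from general knowledge, in part from studies of this cell line, and is therefore not independent evidence of its direction. Of its 25 tested members, 16 fell at 18 h, 17 at 36 h, 19 at 53 h, 20 at 72 h and 20 at 96 h, with the same counts when adjusted over the list alone. The median log2 change went from -1.04 at 18 h to -1.35, -1.17, -1.84 and -2.25 at the later times (camera adjusted p between 4.0e-07 and 0.000198). The adjusted p values with an estimated correlation were 0.0843, 0.156, 0.148, 0.148 and 0.0984, and without the filter on low values the median at 18 h was -0.69. At 96 h BCL11B changed by -3.58 ± 0.19 (SE) and NKX2-2, a homeobox factor, by -2.80 ± 0.16, beside PPP1R1A and PRKCB. Members that rose at 96 h were UPP1, a uridine phosphorylase, by 3.05 ± 0.22, the matrix protein TNC by 1.11 ± 0.16 and the phospholipase PLD2 by 0.62 ± 0.18, chosen for mention after their values were seen.

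Genes known to be repressed by EWS-FLI1 rose, with the same reservation about the list. Of 13 tested, 7 rose at 18 h, 9 at 36 h, 13 at 53 h and 72 h and 11 at 96 h, and 0 fell at any of these times, over all genes and adjusted over the list alone. The median log2 change was 0.79 at 18 h, or 0.65 with dim values set to log2 4, and then 2.27, 3.37, 3.73 and 4.09 (camera adjusted p between 1.6e-07 and 0.000532). It had adjusted p = 0.0720 with an estimated correlation at 18 h and 36 h, and 0.0218 at each later time. Without replicate 1 at 18 h the median at 18 h was 1.30, and without probe sets ending in _x_at or _s_at it was 2.34 at 18 h and 5.11 at 53 h. SPRY1 rose by 6.57 ± 0.30 (SE) and TGFBR2, a receptor for transforming growth factor beta, by 2.54 ± 0.14 at 96 h.

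E2F1 itself fell early and partly returned. Its log2 change was -1.88 ± 0.13 (SE) at 18 h, -3.12 ± 0.13 at 36 h, -3.05 ± 0.15 at 53 h, -3.16 ± 0.15 at 72 h and -1.71 ± 0.15 at 96 h. E2F5 fell at the same times, with -2.15, -2.20, -2.37, -2.75 and -2.54 (SE between 0.15 and 0.17), and 1 of 2 arrays at 72 h was at or above log2 4. With its probe sets averaged E2F5 changed by -1.07, -1.12, -1.20, -1.39 and -1.29. Its other probe set read at most 2.09 on any array, near background, which makes the averaged change smaller. E2F3 fell at all 5 times, with -0.74 ± 0.16 at 18 h, -1.05 ± 0.16 at 36 h and -0.66 ± 0.18 at 96 h, as did E2F6, with -0.43 ± 0.12, -0.78 ± 0.12 and -0.44 ± 0.14. Another probe set of E2F3 had -0.16 at 53 h (adjusted p = 0.315). Without replicate 2 at 96 h the adjusted p at that time was 0.0649 for E2F3 and 0.125 for E2F6, and without replicate 1 at 18 h E2F6 had 0.0742. E2F8, an atypical repressor E2F, had -0.71 at 18 h (limma adjusted p = 0.0538), fell by 3.24 ± 0.26 at 36 h, was at least 12.6-fold lower at 72 h and fell by 1.49 ± 0.29 at 96 h (-0.98 without replicate 2 at 96 h). With the replicate number as a block, E2F8 passed the threshold at 18 h (-0.89, adjusted p = 0.0320), as it did with arrays centred (adjusted p = 0.0450).

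The E2F partner TFDP1 fell, with -0.77 ± 0.16 at 18 h and -1.62 ± 0.16 at 36 h (log2, SE). Its change of -0.46 ± 0.18 at 96 h passed (limma adjusted p = 0.0383) but did not with arrays centred (-0.41, adjusted p = 0.0685), nor without replicate 2, 3 or 4 at 0 h or either array at 96 h (adjusted p between 0.0659 and 0.175). The pocket protein RBL1 had -0.62 at 18 h (adjusted p = 0.0591, and 0.0416 with the replicate block), fell by 2.48 ± 0.23 at 36 h and was at least 8.20-fold lower at 53 h. At 96 h RBL1 fell by 0.91 ± 0.26 (limma adjusted p = 0.0081), which rested on replicate 2 at 96 h (-0.46, adjusted p = 0.197 without it). RB1 fell by 0.68 ± 0.15 at 53 h (-0.44 with its probe sets averaged), and its changes of -0.34 at 36 h and -0.38 at 72 h passed narrowly (adjusted p = 0.0425 and 0.0418) and did not after a second quantile normalization (adjusted p = 0.0729 and 0.0557), and were lost in 9 and 8 of the 16 omissions of 1 array. At 72 h RB1 had -0.60 without replicate 1 at that time and -0.16 without replicate 2 (adjusted p = 0.475). RB1 at 96 h had -0.30 (limma adjusted p = 0.107), and -0.37 with adjusted p = 0.0405 in the block. RBL2 rose at 36 h only among the times against 0 h, by 0.58 ± 0.14, and with arrays centred it also passed at 53 h (0.39, adjusted p = 0.0249) and at 72 h (0.47, adjusted p = 0.0091). TFDP2 fell at 72 h, by 0.69 ± 0.20, with an adjusted p of 0.0595 without replicate 1 at 72 h. The dimmer of its probe sets fell at 36 h, 53 h, 72 h and 96 h, with -0.56, -0.56, -1.19 and -0.89 (limma adjusted p at most 0.0081), while the one used had 0.39 at 36 h. E2F2 and E2F4 were below the filter on low values. Of the 10 tested members of the E2F and RB family, 5, 8, 8, 9 and 7 fell at the 5 times, or 7, 8, 8, 9 and 7 adjusted over the list alone. The list fell at each time (medians -0.66, -1.33, -1.16, -1.02 and -0.56, camera adjusted p between 0.0020 and 0.0219), and centred medians were -0.90 at 72 h and -0.52 at 96 h. The adjusted p with an estimated correlation was 0.156, 0.190, 0.185, 0.209 and 0.247, and without replicate 2 at 96 h the camera adjusted p at that time was 0.0515.

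Targets of E2F in G1/S and DNA replication fell from 18 h on. Of 54 tested, 43 fell at 18 h (46 adjusted over the list alone), 54 at 36 h, 53 at 53 h, 54 at 72 h and 52 at 96 h, and 0 rose. The median log2 change was -0.73 at 18 h, -2.72 at 36 h, -3.04 at 53 h, -3.16 at 72 h and -1.05 at 96 h (camera adjusted p between 3.9e-23 and 4.0e-10). Set with an estimated correlation, the adjusted p values were 0.156, 0.130, 0.148, 0.156 and 0.247. Centred medians were -3.05 at 72 h and -1.01 at 96 h. At 96 h the log2 change was -1.79 ± 0.16 (SE) for the primase subunit PRIM1, -1.43 ± 0.13 for the helicase subunit MCM7, -1.28 ± 0.13 for ATAD2 and -1.37 ± 0.15 for the histone methyltransferase EZH2. CCNE1 and CCNE2, the cyclins E, did not pass at 96 h, with 0.35 (limma adjusted p = 0.593) and -0.057 (adjusted p = 0.906), and were picked out after their values were seen.

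Genes of G2/M and mitosis followed later. At 18 h their median log2 change was -0.044 (camera adjusted p = 0.449), with CDC25B higher by 0.29 ± 0.09, MAD2L1 lower (-0.45 ± 0.12) and 36 of 38 not passing. Adjusted over the list alone, 0 of the 38 passed at 18 h. All 38 fell at 36 h, 53 h, 72 h and 96 h, also adjusted over the list alone, with medians of -1.44, -2.74, -3.56 and -1.33 (camera adjusted p between 1.1e-16 and 1.6e-10). These gave adjusted p = 0.209, 0.156, 0.156 and 0.226 with an estimated correlation, and centred medians were -3.44 at 72 h and -1.28 at 96 h. PTTG1, which guards sister chromatid separation, had a log2 change of -1.55 ± 0.10 (SE) at 96 h, against -1.70 ± 0.14 for CCNB2, -1.68 ± 0.15 for BIRC5 and -1.61 ± 0.15 for the mitotic transcription factor FOXM1. The mean of the E2F targets less the mean of the G2/M genes, per array and relative to 0 h, was -0.71 ± 0.32 at 18 h (SD, n = 3) and -1.21 ± 0.24 at 36 h (SD, n = 3), against an SD of 0.20 at 0 h (n = 4). A two-sided exact permutation test gave p = 0.0286 for each, the lower bound set by 35 splits, and 0.0714 adjusted over the 5 times. That test ignores the pairs taken from the replicate numbers of these times. Within the 3 pairs the difference was -0.80, -0.55 and -0.57 at 18 h and -0.67, -1.44 and -1.31 at 36 h, lower in 3 of 3 at each time. An exact sign-flip test, added after the data were seen, gave a two-sided p = 0.25 for each, the lowest that 3 pairs allow. Replicates 2 and 3 could be 1 RNA, so there may be fewer than 3 independent pairs. The difference was -0.26 at 53 h (exact p = 0.267), 0.49 at 72 h (exact p = 0.0667, the lowest that 15 splits allow) and 0.28 at 96 h (exact p = 0.200).

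**Figure D2:**
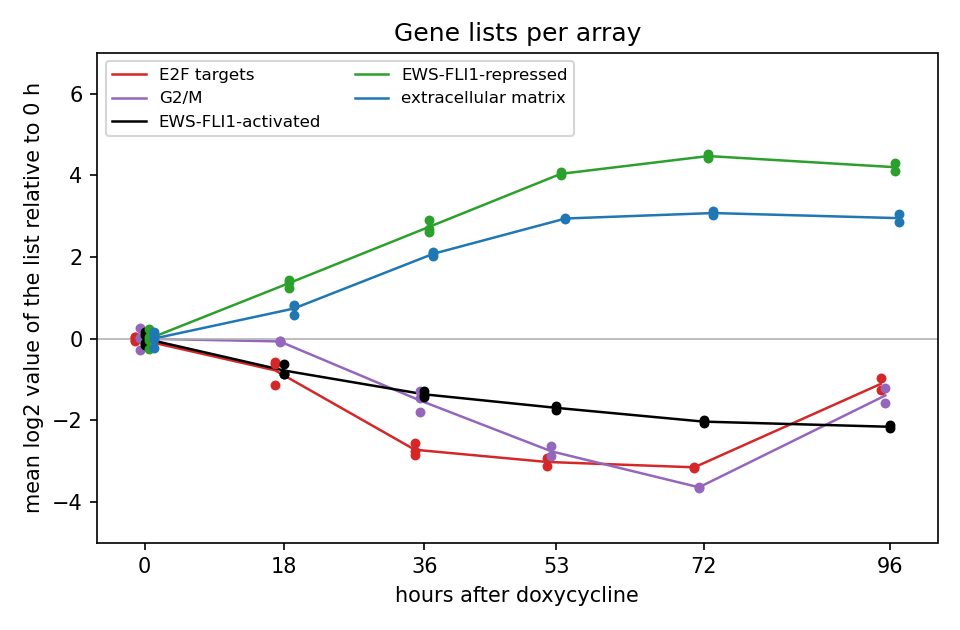
Mean log2 change of each gene list against the 0 h mean (vertical axis) by hours after doxycycline (horizontal axis), with points for arrays, lists set slightly apart, and lines through group means. E2F targets and G2/M genes had their lowest median at 72 h, -3.16 and -3.56, and stood at -1.05 and -1.33 at 96 h.

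Cell cycle genes were higher at 96 h than at 72 h, a comparison added after that return was seen. Of the 54 E2F targets 53 rose, by a median of 2.07 on the log2 scale, and all 38 G2/M genes rose, by a median of 2.18 (n = 2 against 2, camera adjusted p = 6.8e-34 and 2.4e-31), with the same counts adjusted over the list alone. Both had adjusted p = 0.126 with an estimated correlation. E2F1 rose by 1.46 ± 0.17 (SE), RBL1 by 1.98 ± 0.30 and TFDP1 by 0.77 ± 0.20, and E2F8 was at least 4.49-fold higher (limma adjusted p between 3.7e-05 and 0.0134). TFDP1 had an adjusted p of 0.0895 without replicate 1 at 72 h and 0.0639 without replicate 2 at 96 h. FLI1 differed by -0.27 ± 0.19 between these times (adjusted p = 0.322), and the 25 activated targets had a median of -0.12 (camera adjusted p = 0.406). The family median of 0.28, with 4 of 10 members higher, had camera adjusted p = 0.0469, 0.0785 with the replicate block and adjusted p = 0.532 with an estimated correlation. That median was 0.50 without replicate 2 at 72 h, 0.43 without replicate 1 at 96 h (adjusted p = 0.0789) and 0.77 without probe sets ending in _x_at or _s_at, and the call was lost in 11 of the 16 omissions of 1 array (highest adjusted p = 0.0883). In total 1988 genes passed, 1250 higher and 738 lower, or 62.9% higher, against 51.8% higher with arrays centred. The count was 1201 without replicate 1 at 72 h, 1245 without replicate 2 at 72 h and 1244 without replicate 1 at 96 h.

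The comparison of 96 h with 18 h sets late against early knockdown without the 0 h arrays. MGP was at least 635-fold higher, IGFBP3 at least 355-fold, PAMR1 at least 175-fold and FGL2 at least 114-fold, and VCAN rose by 7.95 ± 1.00 (log2, SE, n = 2 against 3). CALCB was at least 9.06-fold lower and TSPAN8, a tetraspanin, at least 14.6-fold lower. The log2 change was -5.22 ± 0.97 for UTS2, -4.43 ± 0.27 for PRKCB and -4.30 ± 0.37 for DKK2 (limma adjusted p at most 0.0026 for each of these genes). VCAN was at or above log2 4 on 1 of 3 arrays at 18 h, and UTS2 changed by -2.62 with its probe sets averaged. All 38 G2/M genes fell, also adjusted over the list alone, with a median of -1.24 (camera adjusted p = 4.8e-12, and adjusted p = 0.209 with an estimated correlation). Of the 54 E2F targets 23 fell and 3 rose by either adjustment, ASF1B (0.49 ± 0.18), CCNE1 (at least 1.85-fold) and CCNE2 (1.68 ± 0.37), named after their values were seen, with a median of -0.40 and a camera adjusted p of 0.0291. That call was lost with an estimated correlation (adjusted p = 0.728), with the replicate block (median -0.36, adjusted p = 0.0925), without the filter on low values (0.136), without probe sets ending in _x_at or _s_at (0.0569), without replicate 2 at 18 h (0.132), without replicate 3 at 18 h (0.129) and without replicate 2 at 96 h (median -0.25, 0.317). In total 3611 genes passed, 1421 higher and 2190 lower.

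Extracellular matrix genes rose from 18 h on. Of 25 tested, 11 rose at 18 h (19 adjusted over the list alone), 23 at 36 h, 24 at 53 h and 72 h and 22 at 96 h, with medians of 0.72, 1.75, 2.67, 2.63 and 2.56 (camera adjusted p between 7.4e-13 and 2.2e-06). With dim values at log2 4 the median at 96 h was 2.41. The list had adjusted p = 0.104 with an estimated correlation at 18 h, 0.0720 at 36 h and between 0.0238 and 0.0357 at later times. With all probe sets averaged the median at 18 h was 0.41, and without probe sets ending in _x_at or _s_at it was 0.31 at 18 h and 1.74 at 53 h. At 96 h the collagens COL1A2, COL6A2 and COL4A2 rose by 4.38 ± 0.15, 3.94 ± 0.12 and 2.41 ± 0.13 (SE), and the matrix protease MMP2 by 3.10 ± 0.15. MMP1, a collagenase, singled out after its values were seen, fell at 36 h, 53 h and 72 h, with -0.83 ± 0.17, -0.48 ± 0.20 and -0.55 ± 0.20. COL6A2 rose by 2.37 with its _x_at and _s_at probe sets left out.

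Genes of mesenchymal progenitors, bone, cartilage and fat rose as well. Of 11 tested, 4, 8, 8, 9 and 9 rose at the 5 times, or 4, 8, 9, 9 and 9 adjusted over the list alone, with medians of 0.14, 1.17, 2.27, 2.97 and 2.99 (camera adjusted p between 9.1e-06 and 0.0142). The adjusted p with an estimated correlation was 0.104, 0.0782, 0.0332, 0.0218 and 0.0218. Without the filter on low values, which adds dim members, the medians were 0.011, 0.094, 0.36, 0.86 and 0.94, and the call at 18 h was lost (adjusted p = 0.0720). The 4 members that rose at 18 h, named after their values were seen, were PDGFRA, SOX9 (1.65 ± 0.15), VCAM1 (2.52 ± 0.31) and PDGFRB (0.95 ± 0.14), and the median at 18 h was 0.27 with the replicate block. It was 0.39 without replicate 1 at 18 h, 0.23 without replicate 2 and 0.22 without replicate 3 at 18 h, and 0.23, 0.23 and 0.27 without replicates 2, 3 and 4 at 0 h. At 96 h SPP1, the gene of osteopontin, and PDGFRA were among the genes that rose, PDGFRA at least 75.3-fold by the probe set used, or by 2.88 on the log2 scale with its probe sets averaged. VCAM1, at or above log2 4 on 3 of 4 arrays at 0 h, rose by 3.52 ± 0.35 (SE) and the cartilage factor SOX9 by 2.67 ± 0.18. ALPL, alkaline phosphatase, went the other way and was at least 1.75-fold lower at 96 h (limma adjusted p = 0.0245), a member singled out afterwards.

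Actin cytoskeleton and adhesion genes rose later, 9 of 17 at 53 h and 14 at 72 h and 96 h, with the same counts adjusted over the list alone. Their medians were 0.50, 0.90 and 1.03 (camera adjusted p = 0.0260, 0.000481 and 1.9e-05, and adjusted p = 0.457, 0.209 and 0.156 with an estimated correlation). The call at 53 h was lost without replicate 2 at 53 h (adjusted p = 0.0622), and the median at 53 h was 0.87 without probe sets ending in _x_at or _s_at. The integrin subunits ITGAV and ITGA5 rose by 2.83 ± 0.15 and 2.13 ± 0.12 (SE) at 96 h, and ITGA2 was at least 2.27-fold higher. ITGB1 rose by 0.99 ± 0.08, or 0.16 with all its probe sets averaged, which missed the threshold (adjusted p = 0.0610). Only 1 of its 5 probe sets reached the filter on low values.

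Ribosome biogenesis genes fell at every time, 20 of 23 at 18 h, 22 at 36 h and 53 h and 23 at 72 h and 96 h, also adjusted over the list alone, with medians of -0.79, -1.29, -1.13, -1.23 and -1.08 (camera adjusted p between 8.3e-13 and 1.0e-06, and adjusted p between 0.130 and 0.209 with an estimated correlation). Without probe sets ending in _x_at or _s_at the median at 36 h was -2.02. At 96 h UTP20 changed by -1.86 ± 0.20 (SE), WDR12 by -1.29 ± 0.12, GAR1 by -1.08 ± 0.11 and fibrillarin (FBL) by -0.54 ± 0.05. Mitochondrial ribosome and translation genes fell too, 9, 23, 26, 28 and 27 of 28, the same adjusted over the list alone, with medians of -0.15, -0.66, -0.82, -1.18 and -0.69 (camera adjusted p at most 0.0064, and adjusted p = 0.294, 0.130, 0.111, 0.0884 and 0.104 with an estimated correlation). At 96 h MTIF2 changed by -1.08 ± 0.09, MRPL42 by -1.07 ± 0.10, MRPS15 by -0.96 ± 0.09 and MRPS27 by -0.95 ± 0.09. With arrays centred the medians of the mitochondrial list were -1.06 at 72 h and -0.65 at 96 h, and those of the ribosome biogenesis list -1.11 and -1.04. Respiratory chain genes fell at 53 h, 72 h and 96 h (15, 23 and 24 of 28, and 15, 23 and 25 adjusted over the list alone), with medians of -0.28, -0.51 and -0.35, or -0.39 at 72 h and -0.31 at 96 h with arrays centred. Their camera adjusted p was 0.0246, 0.000256 and 0.000255, against adjusted p = 0.476, 0.209 and 0.209 with an estimated correlation. The call at 53 h was lost after a second quantile normalization (adjusted p = 0.0658), and the median at 96 h was -0.23 without replicate 1 at 96 h. At 96 h CYC1, cytochrome c1, changed by -0.67 ± 0.08, NDUFA8 by -0.64 ± 0.09, NDUFA9 by -0.53 ± 0.07 and COX5A by -0.44 ± 0.06.

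Integrated stress response genes rose from 18 h to 72 h, in 9, 19, 17 and 9 of 27 members (9, 19, 17 and 8 adjusted over the list alone), with medians of 0.58, 1.09, 1.06 and 0.47 (camera adjusted p = 0.000613, 0.0019, 0.000954 and 0.0298). They had adjusted p = 0.554, 0.574, 0.568 and 0.717 with an estimated correlation, and with arrays centred the camera adjusted p was 0.0604 at 72 h. Arrays of a group differed widely here, the mean of the list at 36 h being 0.16 above 0 h in replicate 1 against 2.24 and 2.28 in replicates 2 and 3. Replicates 2 and 3 were nearly alike and could be 1 RNA, so the rise at 36 h may rest on a single RNA. At 96 h the median was -0.17 (camera adjusted p = 0.682), although NUPR1 rose by 4.27 ± 0.80 (SE), DDIT4 by 3.61 ± 0.59, SLC7A11 by 0.70 ± 0.18 (adjusted p = 0.0661 without replicate 1 at 96 h) and VLDLR was at least 4.37-fold higher. NUPR1 was at or above log2 4 on 1 of 4 arrays at 0 h.

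Interferon response genes rose by medians of 0.34, 0.68, 0.93, 0.86 and 0.78 at the 5 times, with 5, 11, 11, 9 and 9 of 17 higher (5, 11, 11, 9 and 11 adjusted over the list alone) and camera adjusted p between 0.0056 and 0.0219. Many members lay near background, and with dim values at log2 4 the medians were 0.11, 0.38, 0.23, 0.18 and 0.16, or 0.032, 0.30, 0.19, 0.078 and 0.13 without the filter. Without probe sets ending in _x_at or _s_at the median at 36 h was 1.11. The call was lost at all 5 times with the stricter filter of log2 6 (adjusted p between 0.0871 and 0.479), at 18 h without replicate 1 at 18 h (0.0797), with the median at 0.22, and with an estimated correlation (adjusted p between 0.179 and 0.227). Setting dim values to log2 4 also ended it at 18 h, 36 h, 53 h and 72 h (adjusted p between 0.0656 and 0.157). The 5 members that rose at 18 h, named after their values were seen, were IFI44L, IFIT1, DDX60, IFI44 and ISG15, of which IFIT1 and DDX60 were below log2 4 on all 4 arrays at 0 h. IFIT1 averaged 3.94 at 18 h, below log2 4 as well, so no fold is given. IRF9, a factor of interferon signalling that was at or above log2 4 on 2 of 4 arrays at 0 h, rose by 3.10 ± 0.36 (SE) at 96 h, OAS1 was at least 2.99-fold and IFIT3 at least 1.92-fold higher, and USP18, which dampens interferon signalling, fell by 1.32 ± 0.13.

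Neural genes rose at 18 h and 36 h, 6 and 7 of 13 (6 and 8 adjusted over the list alone), with medians of 0.24 and 1.63 (camera adjusted p = 0.0213 and 0.0274, and adjusted p = 0.313 and 0.341 with an estimated correlation). Without replicate 1 at 36 h the adjusted p at 36 h was 0.0691, with all probe sets averaged it was 0.0737 at 18 h and 0.0724 at 36 h, and without replicate 1 at 18 h the median at 18 h was 0.12. Without the filter on low values the medians were 0.013 and 0.088, and without probe sets ending in _x_at or _s_at the median at 18 h was 1.03. At 96 h the list did not pass by camera (median 0.47, adjusted p = 0.129) and passed as higher by fry, which does not compare it with other genes (adjusted p = 9.4e-05), as it did at 53 h and 72 h (fry adjusted p = 0.000293 and 0.0012). Over the alternatives the median at 96 h ran from -0.027 to 1.49. At 96 h the axonal growth gene GAP43 rose by 4.72 ± 0.16 (SE), NEFL by 4.16 ± 0.39 and L1CAM by 4.09 ± 0.26, and the synaptic gene SYT1 fell by 1.04 ± 0.13. With their probe sets averaged L1CAM rose by 2.39 and NEFL by 2.66, where 1 of 2 probe sets of L1CAM and 3 of 3 of NEFL reached the filter.

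Glycolysis and hypoxia genes rose at 96 h, 13 of 25 (also adjusted over the list alone), by a median of 0.26, or 0.31 with arrays centred (camera adjusted p = 0.0067, adjusted p = 0.209 with an estimated correlation and 0.191 without probe sets ending in _x_at or _s_at). The collagen hydroxylases P4HA2 and P4HA1 rose by 5.07 ± 0.44 and 1.55 ± 0.18 (SE), the glucose transporter SLC2A3 by 1.29 ± 0.19 and NDRG1, at or above log2 4 on 2 of 4 arrays at 0 h, by 2.65 ± 0.39. Cholesterol synthesis genes passed at 18 h among the times against 0 h (median 0.26, camera adjusted p = 0.0117, and adjusted p = 0.568 with an estimated correlation). The 3 of 15 members that rose at 18 h by either adjustment, named after their values were seen, were INSIG1 (1.13 ± 0.28), LSS (0.89 ± 0.15) and HMGCS1 (0.81 ± 0.26). At 96 h FDPS changed by -0.45 ± 0.11 and EBP by -0.69 ± 0.16, while INSIG1 rose by 1.03 ± 0.32. INSIG1 had 0.68 with an adjusted p of 0.176 without replicate 1 at 96 h, and ACAT2, with -0.74 ± 0.25, had 0.115 without the same replicate and 0.0540 without replicate 2. Targets of p53, which A673 cells lack in working form, did not pass as a list by camera at any time (median -0.078 at 96 h, camera adjusted p = 0.780). By fry they passed as higher at 36 h and 53 h (adjusted p = 5.6e-06 and 0.000113) and as lower at 96 h (adjusted p = 0.0053).

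Markers of blood cells and epithelial cells stayed below the filter on all 16 arrays, with highest values of 3.80 (CORO1A, of 16 markers) and 3.54 (KRT7, of 17). Of 9 endothelial markers 2 were tested, EMCN and KDR, and both rose at 36 h to 96 h, EMCN by 2.16 ± 0.26 (SE) at 72 h and KDR at least 23.8-fold at 53 h.

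Of all genes tested, 6137 changed over the time course by the moderated F test of limma, and 3158 of them by at least 1 on the log2 scale at some time. Of the genes called at 18 h, 1464 were called at 96 h in the same direction and 140 in the opposite one. Independent lists of these sizes would share 653. Comparisons with the same 0 h arrays share their chance values. In a simulation without any change, all arrays, those at 0 h included, were drawn anew around the 0 h means. It gave 0.06 and 0.04 calls per run over 50 runs and shared 0, too few to show what shared arrays add. With separate 0 h arrays for each time 890 to 1105 genes were shared, against 334 to 497 expected of independent lists, 890 going with 334 and 1105 with 497. Across genes, which are not independent replicates, the changes at 18 h and 96 h had a covariance of 0.347 against 0.0184 in the simulation and a correlation of 0.531 against 0.378. Simulated noise was independent between arrays, unlike the deviations of the real arrays, so these are limited references.

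**Figure D3:**
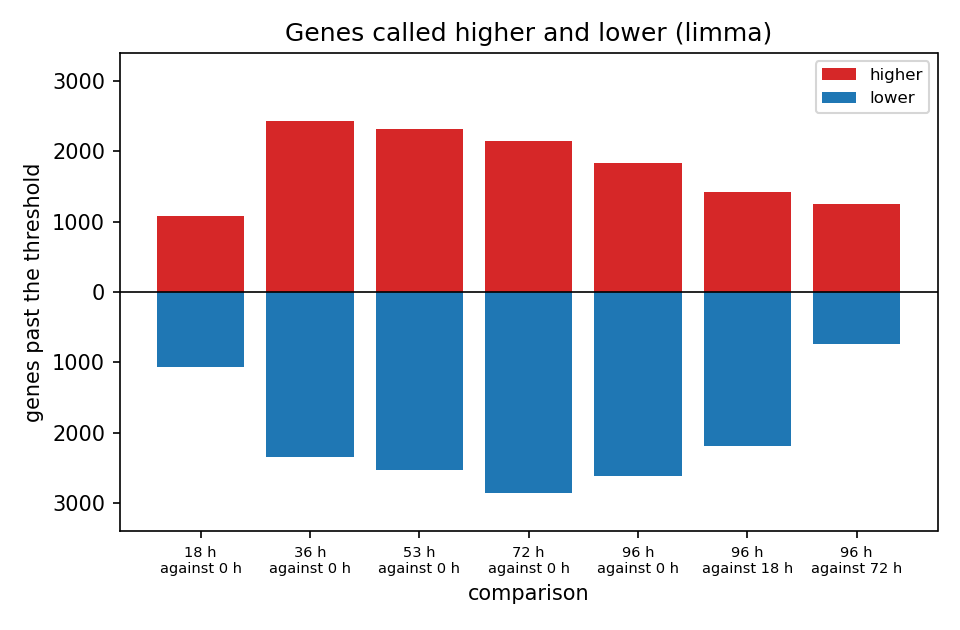
Number of genes with limma adjusted p below 0.05 (vertical axis) in each comparison (horizontal axis: each time against 0 h, and 96 h against 18 h and 72 h), with bars up for higher and down for lower genes. The 72 h bars hold 2142 higher and 2861 lower genes.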

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

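The test of renewed EWS-FLI1 expression, that of 1 RNA on 2 arrays and that of the covariance across probe sets were chosen only after the results were seen, as was the comparison of 96 h with 72 h.

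Cell cycle genes were higher at 96 h than at 72 h, with median log2 changes of 2.07 for the E2F targets and 2.18 for the G2/M genes. Cells that had regained EWS-FLI1 might explain this, but FLI1 regained none of its fall from 0 h to 72 h. On the linear scale its brightest probe set regained -0.71% and -3.76% on the 2 arrays at 96 h. The lists had regained at least 27.4% of their fall, with an SD between arrays of up to 9.30 percentage points. As a level, FLI1 stood at no more than 17.4% of 0 h in any probe set at 96 h, the highest in a probe set below log2 4. Scaling between arrays is argued against, since the median rise of the E2F targets was 2.00 at the lowest after a second quantile normalization or centring. A difference between array batches stays open, since replicates 1 and 2 are at both times and the rise of at least 1.94 in each pair of arrays with the same number cannot test a batch between times, and the labels name no batch. A change of medium, cell density and doxycycline itself stay open and untested.

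Replicate 4 at 0 h and replicate 2 at 53 h and at 96 h deviated from their groups alike, with correlations across genes of 0.279, 0.260 and 0.248. An array or labelling batch specific to probe sets is a candidate explanation, since the covariance between these arrays across 2 probe sets of a gene was 0.084 of that for the same probe set (bootstrap limits -0.014 and 0.178, 1022 genes). For arrays of replicates 1, 2 and 3 at 0 h, 18 h and 36 h that ratio was 0.885, 0.743 and 0.856. The mean deviation of the 3 arrays correlated at 0.264 between 2 probe sets, which decides little, as differences between replicates gave 0.091 at 53 h and 0.783 for replicates 1 and 2 at 0 h. The 3' less the 5' signal of GAPDH, like that of ACTB a measure of RNA quality, was 0.068, 0.073 and 0.050 on these 3 arrays (log2). It was 0.031 on replicate 2 at 72 h and lay between 0.122 and 0.223 on every other array. Whether this goes with the shared deviation was not tested. The labels give no batch, and no biological explanation was tested.

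Replicates 2 and 3 at 0 h, 18 h and 36 h were nearly alike, with an SD of the log2 difference of 0.176, 0.164 and 0.186. They could be 1 RNA on 2 arrays. Differences between them correlated over 2 probe sets of 1 gene at 0.156 or more, above the highest permuted value at each time (0.111, 0.083 and 0.099), which goes against a single RNA hybridised repeatedly. Separate labellings of 1 RNA can also leave differences per gene, so that bound does not settle the matter and it stays open. With these replicates averaged, the count at 18 h was 1269, and calls were lost for RB1 at 36 h and 72 h (limma adjusted p = 0.149 and 0.0893), TFDP1 at 96 h (0.0809), E2F targets for 96 h against 18 h (median -0.30, camera adjusted p = 0.112), and the E2F and RB family and ribosome biogenesis genes for 96 h against 72 h (0.0512 and 0.0534). The 2 arrays at 53 h and at 72 h could each be 1 RNA too, with SDs of 0.285 and 0.234. Their differences correlated at 0.091 at 53 h, within the permuted range (highest 0.095), and at 0.135 at 72 h, just above it (0.122). This stays open, and those arrays are the only ones at their times.

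With the 7 arrays taken as unpaired and separate samples, every other grouping gave fewer genes than the real one at 18 h and at 36 h. Whether replicates 2 and 3 were separate RNA stays open, so these splits cannot exclude chance. Only 1 of 35 splits of the 7 arrays gave as many genes at 18 h, the real one with 2150, and the highest other gave 1111. At 36 h it was again 1 of 35, with 4772 against 3390. Both highest other splits kept replicates 2, 3 and 4 of 0 h together. If replicate numbers pair these arrays, the 8 splits that parted all 3 pairs are too few for a share under 0.05. Among them the real counts stood against 48 and 2563 at the highest, in splits that differed from the real one by replicate 4 at 0 h, and the rest gave 0.

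Single arrays stood apart at 0 h for some results, by the gap to the nearest array over the range of the 4. For 4 independent arrays chance alone gives this in about 1 in 20 groups. Of these arrays 2 were nearly alike and could be 1 RNA, so chance may give it more often here. A single array stood apart for 4 of 18 lists, 12 of 102 genes and 0 of 6 array measures. Of these, 9 of the 12 genes and 2 of the 4 lists had replicate 4 apart. Whether these counts exceed chance cannot be told from the share of 1 in 20. Replicate 4 was lowest for the E2F and RB family (0.844), cholesterol synthesis genes (0.857), MCM10 (0.968), PLK1 (0.845) and RBL1 (0.879). It was highest for MGP (0.866), IGFBP3 (0.905), PAMR1 (0.985), DKK1 (0.871), IGFBP5 (0.837) and MRPL42 (0.964). Replicate 1 was lowest for actin and adhesion genes (0.854) and MRPS15 (0.867), and highest for interferon genes (0.857), DLG2 (0.878) and DDIT4 (0.927). MGP, IGFBP3, PAMR1 and DKK1 were below log2 4 on every array at 0 h.

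Lists also differed between times by camera. From 18 h to 96 h the median log2 change was -1.10 for activated and 1.72 for repressed targets of EWS-FLI1, -0.40 for E2F targets, -1.24 for G2/M genes, 2.12 for matrix genes, 0.82 for actin and adhesion genes, 1.90 for mesenchymal genes, -0.43 for respiratory chain genes, -0.67 for mitochondrial ribosome genes and 0.22 for glycolysis and hypoxia genes. With an estimated correlation the repressed, matrix and mesenchymal lists kept their calls (adjusted p at most 0.0238), while adjusted p = 0.148 for activated, actin, respiratory chain and mitochondrial ribosome genes, 0.209 for G2/M genes, 0.234 for glycolysis genes and 0.728 for E2F targets. The mesenchymal median was 1.02 with probe sets averaged and 0.41 without the filter, and that of glycolysis 0.36 without replicate 1 at 18 h. From 72 h to 96 h the median log2 change was 0.28 for the E2F and RB family, -0.55 for integrated stress response genes, 0.38 for mitochondrial ribosome genes and 0.27 for ribosome biogenesis genes, of which the last was 0.11 with adjusted p = 0.569 without replicate 1 at 96 h and had adjusted p = 0.0566 with the replicate block. The calls of the family and of ribosome biogenesis were each lost in 11 of the 16 omissions of 1 array. With an estimated correlation the adjusted p was 0.532, 0.680, 0.257 and 0.680.

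Outside the named genes, 648 of 1316 tested probe sets without a single gene name changed at 96 h against 0 h by limma, 238 higher and 410 lower.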

How the results depend on the processing

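The averaged replicates, the inferred batch, dim values at log2 4, the joint omission of 3 arrays, the differences within replicate pairs and the comparison of 96 h with 72 h were chosen only after the data were seen. Over 273 results and 40 alternatives, 16 of them omissions of 1 array, FLI1 kept its direction and side of the threshold in all 70 values, and in all 80 with 1 array omitted. With an omitted array leaving 1 sample in a group, that sample is assumed to vary like the others. Dim signal limits genes near background.

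In the comparisons with 0 h only, lists of EWS-FLI1 and E2F targets kept theirs in 228 of 240 values. With an array omitted they kept them in 240 of 240. The other 12 were lost with an estimated correlation, which allows for members moving together. They had medians of -1.04, -1.35, -1.17, -1.84 and -2.25 for activated genes from 18 h to 96 h, -0.73, -2.72, -3.04, -3.16 and -1.05 for E2F targets, and 0.79 and 2.27 for repressed genes at 18 h and 36 h. Outside these comparisons, the E2F targets for 96 h against 18 h lost their call in 3 of the 16 omissions of an array.

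Requiring a log2 change of at least 1 left 400, 1883, 2185, 2451 and 1673 genes from 18 h to 96 h, 1175 for 96 h against 18 h, 659 against 72 h and 3158 over the time course, by construction. Without probe sets ending in _x_at or _s_at fewer genes were tested, and 1320, 2854, 2932, 3019, 2694, 2107, 1123 and 3675 passed. At 18 h array weights gave 3546 and averaged replicates 1269, and omitting 1 array gave 1355 to 2441. For 96 h against 72 h omissions gave 1201 to 2223. Overlap with split controls fell to 890 and 895. The cause was not tested.

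Changes of named genes that turned direction were not past the threshold either way. For RBL2, 96 h against 0 h, they were -0.13 with the replicate block, -0.13 with probe sets averaged, -0.013 with 3 arrays omitted and -0.055 to 0.14 with 1 omitted. For TFDP2, 36 h against 0 h, it was -0.088 with probe sets averaged. For TFDP2, 53 h against 0 h, they were 0.051 with the inferred batch, 0.11 with 3 arrays omitted and -0.22 to 0.15 with 1 omitted. For RB1, 18 h against 0 h, they were -0.14 to 0.0028. Medians of some lists at 96 h against 0 h also took both signs over the alternatives. They ran from -0.027 to 1.49 for neural genes, -0.22 to 0.0057 for p53 targets and -0.13 to 0.081 for cholesterol synthesis genes. The cause was not tested. The replicate block otherwise changed the calls of E2F8 and RBL1 at 18 h, RB1 at 96 h, E2F targets for 96 h against 18 h, and the family and ribosome biogenesis genes for 96 h against 72 h (0.28 and 0.27), and no other call among these results. Numbers at 53 h, 72 h and 96 h, with 2 arrays each, were too few to be taken as pairs (correlations of 0.0026 for 53 h with 72 h, 0.248 for 53 h with 96 h and 0.158 for 72 h with 96 h), and 10 of 16 arrays correlated best with their own number.

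The other list results include the EWS-FLI1 and E2F target lists where the comparison was not with 0 h. Of their values 980 held, 100 were lost and 2 gained (neural genes and p53 targets at 96 h against 0 h, by fry). Losses were not spread evenly over the alternatives. With an estimated correlation 67 of all 83 list results, the EWS-FLI1 and E2F targets against 0 h included, lost their call and 16 held. Of named genes 2335 held, 21 were lost and 33 gained. With 1 array omitted it was 1059 held and 29 lost for lists, and 2757 held, 33 lost and 18 gained for genes.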

Other observations

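Members of some lists parted at 96 h against 0 h, as seen after their values were known. Among integrated stress response genes, PSAT1 had a log2 change of -2.07 ± 0.61 (SE), PHGDH -0.92 ± 0.34, SLC7A5 -1.79 ± 0.60, SLC3A2 -1.15 ± 0.45 and the transcription factor ATF3 -0.73 ± 0.23 (limma adjusted p between 0.0095 and 0.0415). SLC7A11, another amino acid transporter gene, rose by 0.70 ± 0.18. From 72 h to 96 h GDF15, at or above log2 4 on 1 of 2 arrays at 96 h, changed by -5.50 ± 0.78 and ATF3 by -1.37 ± 0.26.

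Among p53 targets TP53I3, at or above log2 4 on 1 of 4 arrays at 0 h, rose by 3.08 ± 0.32 and ZMAT3 by 0.73 ± 0.16 at 96 h, while FAS, a death receptor, changed by -1.90 ± 0.21, AEN by -1.79 ± 0.33, CCNG1 by -0.75 ± 0.10 and BAX by -0.38 ± 0.16 (limma adjusted p at most 0.0485). Among neural genes the neuropeptide gene NPY changed by -3.78 ± 0.57, SNAP25, at or above log2 4 on 1 of 2 arrays at 96 h, by -1.02 ± 0.30 and TUBB3 by -0.32 ± 0.10.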
